A study of Homo sapiens with 8 samples.

How the data were processed

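RNA-seq of 8 libraries was used, 1 library of control siRNA and 1 of PDX1 siRNA for each of 4 human PDA cell lines, collected 3 days after transfection. Line names are written without the dot that the sample titles put after Panc. Per the submitters' processing notes, TopHat2 (version 2), Cufflinks and Cuffdiff were used and the genome build was hg38. The role of each tool, the gene annotation, the strandedness of the libraries and the versions of Cufflinks and Cuffdiff are not given in the sources used here. Each line had its own table of 28520 rows. Per the file headers, the authors deposited an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments) for the control and for the PDX1 siRNA library, with a p-value, a q-value and a test status from Cuffdiff. The p-values and q-values in the authors' deposited tables compare 2 libraries and not the conditions, and they are quoted as theirs at a q threshold of 0.05. FPKM values are not counts, so no count model was used. Whether the 4 tables were scaled together is not stated, so differences were taken within a table, and a level set across tables carries that limit.

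Rows were joined over the 4 tables by the row identifier. 24156 rows had a symbol of their own, 4011 shared a symbol with another row, 528 held several symbols and 28 had a symbol that a spreadsheet had turned into a date. A RefSeq gene type was found for 26778 rows (93.9%) by symbol or synonym, 20122 of them protein-coding. Of 21667 rows compared with RefSeq, the start was 1 lower than the annotated start in 6164 and equal to it in 585, and the others matched neither way. Starts were therefore read as counted from 0, and 1 was added to print the PDX1 position. The status was OK for between 12027 and 12585 rows of a table, and 0 to 19 rows were marked as having too much data. FPKM values of the smallest rows cluster at whole-number ratios, and the commonest ratio between the 2 libraries of a line, among rows under 0.15 FPKM in both, gave the relative depth. Total depth stayed unknown, and no counting interval is given. Any 2 libraries had equal values in at most 0.00891% of the rows above 1 FPKM.

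Log2 ratios of PDX1 siRNA over control siRNA were taken on log2(FPKM + 1), which understates changes of genes with low FPKM. Across lines, genes with a mean FPKM of at least 1 over the 8 libraries (12110) were fitted with limma 3.58.1 in R 4.3.3, with the cell line as a block and eBayes with trend, and p-values were adjusted by Benjamini and Hochberg. This left 3 residual degrees of freedom and 2.94 prior degrees of freedom. The pairing comes from the labels, which give the cell line of each library. Libraries of a line correlated in their deviations from the group means (r between 0.844 and 0.963), and libraries of different lines did not exceed -0.152. Subtracting a mean over only 4 lines pushes the values between lines below 0, so their sign is no evidence for the pairing. PDX1 was tested with an exact two-sided sign-flip permutation test of the 4 ratios over 16 sign patterns. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. Within a line no test was made: a row counted as 2-fold higher or lower when its log2 ratio reached 1 and it had at least 1 FPKM in either library. There a list's median was set against medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest. P-values of single genes measure the spread between the 4 lines. Those of camera with a preset correlation compare the genes of a list with the other genes and do not measure that spread for the list.

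The tests, the alternatives, the gene lists and the rule for named genes were written before the data were examined. Named genes were PDX1; across lines, the 12 genes per direction with the largest mean log2 ratios past adjusted p 0.05 and the same sign in 4 lines, and otherwise those with the smallest unadjusted p and the same sign; for each list, up to 4 members with the largest mean log2 ratio; and for each line, the 6 highest and 6 lowest ratios among rows with at least 5 FPKM in either library and status OK. That last part took mostly small RNAs listed at 0 in 1 library. Therefore, after the values were seen, the 12 highest and 12 lowest protein-coding genes above 0 FPKM in both libraries of a line were added, and most genes named within a line come from there. Rows without a symbol of their own and sex-linked genes were not named, and some genes that the rule took are not reported here. The members of a list named within a line were taken from those parts or were chosen after their values were seen (ISG15 and CXCL10 belong to the added part; HELLS, UHRF1, ODC1, LDHA, ACTB, GAPDH, PLK1 and AURKA to the list part).

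The across-line test and the list test were tested on simulated data with 200 changed genes among 12110. Recovery was 40% at a log2 change of 0.5, 84% at 1, 98% at 2 and 100% at 3, with 6 false calls among 11910 unchanged genes. Because the 200 genes were changed at once, the adjusted threshold was easier to pass than with a few changed genes. Recovery of a few changed genes is therefore not shown. A list shifted by -0.5 was recovered, and 0 of the other lists were called. Noise was drawn independently for each gene, while the estimated correlation in the data was 0.902 for interferon-stimulated genes and 0.884 for G1/S genes. The simulation therefore cannot show how often camera with a preset correlation calls lists falsely in these data. In simulated agreement data, 49 of 50 genes raised by 2 on the log2 scale in every line were found. That size was well above the 1.5-fold threshold, so recovery of smaller shared changes is not shown. Alternatives were other pseudocounts (0.1 and 5), no filter or a filter of 5 FPKM, no block, centred ratios, quantile normalization, rows with status OK, eBayes without trend or robust, leaving out each line, and for the per-line counts the authors' own calls and 1.5-fold. Counts over protein-coding rows and counts and agreement without the interferon-stimulated list were added after seeing the data. Mitochondrially encoded genes had 0 rows in these tables, and endocrine, acinar, fibroblast, leukocyte and endothelial lists had fewer than 5 tested members, so these were not tested.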

Results

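The data were 8 RNA-seq libraries from 4 established human pancreatic ductal adenocarcinoma (PDA) cell lines, Panc8, HPAF-II, Panc05.04 and Panc10.05. Cells of each line received either a control small interfering RNA (siRNA) or an siRNA against PDX1, a homeobox transcription factor of pancreas development and of the adult islet, and were collected 3 days after transfection. There was 1 library per line and treatment, so the 4 lines were the replicates of the treatment and no line had a replicate of its own. Values were FPKM from the authors' table of 28520 rows for each line. The FPKM of a library summed to between 371329 and 428778, and between 11186 and 11477 rows reached 1 FPKM. Total read numbers were not given in the sources used here. From the spacing of the lowest values, the depth of the PDX1 siRNA library relative to its control was estimated as 0.642 in Panc8, 1.40 in HPAF-II, 0.838 in Panc05.04 and 0.956 in Panc10.05. These estimates are unsure, since a second, less common spacing would give 1.28, 0.707, 1.68 and 1.91 in the same lines. Its density was 0.653 of the first in Panc8, 0.467 in HPAF-II, 0.424 in Panc05.04 and 0.383 in Panc10.05.

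PDX1 itself was lower with PDX1 siRNA in all 4 lines. In HPAF-II, the line with the highest PDX1 level, it was 9.61 FPKM with control siRNA and 5.37 FPKM with PDX1 siRNA, 55.9% of control. In Panc05.04 it was 1.41 and 0.416 FPKM, 29.55% of control, and in Panc8 0.914 and 0.372 FPKM, 40.7% of control. In Panc10.05 PDX1 was close to the detection floor in both libraries, 0.188 and 0.0998 FPKM. The mean log2 ratio of FPKM + 1 was -0.52 ± 0.30 (SD, n = 4 lines), and the exact two-sided sign-flip permutation test gave p = 0.125, the smallest p that 4 pairs allow. The ratio of FPKM without a pseudocount was -1.20 ± 0.42 on the log2 scale (SD, n = 4). The files place the PDX1 row (XLOC_006631) on chromosome 13 between 27829759 and 27926314 of hg38, an interval that also takes in the antisense gene PDX1-AS1. PDX1-AS1 had a row of its own, at 0.391 FPKM or less in each library. Antisense reads cannot be told apart from PDX1 reads unless strand was used in counting, which the sources used here do not state. The authors' deposited table gave PDX1 an unadjusted p of 0.094 in Panc8, 0.0044 in HPAF-II and 0.02035 in Panc05.04, with q of at least 0.998, and marked Panc10.05 as not tested. Levels in different lines come from tables that may have been scaled separately.

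**Figure D1:**
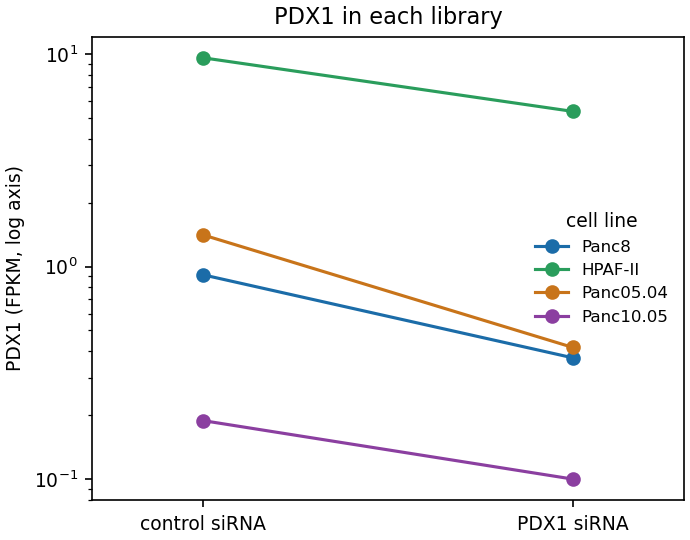
PDX1 level in FPKM (log axis) in the control siRNA and PDX1 siRNA library of each of the 4 lines, with 1 library per point and lines joining the 2 libraries of a cell line. PDX1 was lower with PDX1 siRNA in all 4 lines, from 9.61 to 5.37 FPKM in HPAF-II and from 0.188 to 0.0998 FPKM in Panc10.05.

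The comparison across lines asked which transcripts differed between PDX1 siRNA and control siRNA in the same direction in the 4 lines. Of the 12110 genes tested, 0 were higher and 0 were lower at an adjusted p of 0.05 (limma with the line as block), and the smallest adjusted p was 0.898. At an unadjusted p under 0.05, limma gave 440 genes, 245 higher and 195 lower, where chance gives 605.5. The same sign in all 4 lines was found for 1604 genes, 902 higher and 702 lower, or 13.2% of those tested against 12.5% by chance. In data simulated with the spread of these libraries, the same test recovered 84% of genes changed by 1 on the log2 scale and 40% of those changed by 0.5.

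The genes with the smallest unadjusted p and the same sign in 4 of 4 lines are named here although none passed the adjusted threshold. SAA1, the acute-phase serum amyloid A, had the largest mean difference among the 12 higher genes, with a log2 ratio of 1.56 ± 0.80 (SD, n = 4). Its FPKM was 14.2 and 43.2 in Panc8, 2.52 and 4.41 in HPAF-II, 136 and 390.1 in Panc05.04, and 14.1 and 88.3 in Panc10.05, with control siRNA and PDX1 siRNA respectively. NEURL3, a ubiquitin ligase, had a log2 ratio of 0.98 ± 0.45 and ADM, the hypoxia-responsive vasodilator peptide adrenomedullin, 0.90 ± 0.49 (SD, n = 4). SYTL3, a Rab effector of vesicle transport, had 0.66 ± 0.37, GOLT1A 0.55 ± 0.26 and the antisense gene EML2-AS1 0.54 ± 0.18. STOM, TECPR2, the calcineurin regulator RCAN1, CFDP1 and RNF149 had mean log2 ratios between 0.31 and 0.45. Among the 12 lower genes, the mitotic kinase AURKA had a log2 ratio of -0.49 ± 0.24 and the mitotic kinesin KIF20A -0.43 ± 0.22 (SD, n = 4). SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, had -0.59 ± 0.21, and AKR1C1, an aldo-keto reductase, -0.45 ± 0.22. CD109, a surface protein that binds TGF-beta, was close to the same in each line, between -0.51 and -0.34. ANAPC15, a subunit of the anaphase-promoting complex, lay between -0.44 and -0.33. BCL7C, PXMP2, the readthrough gene DTX2P1-UPK3BP1-PMS2P11, KDELC2 and UBE3C had mean log2 ratios between -0.48 and -0.31. The small nucleolar RNA SNORA63 had the lowest mean, -3.73 ± 1.54, and was listed at 0 in 3 of the PDX1 siRNA libraries.

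Of 35 gene lists fixed before the data were examined, 29 had at least 5 tested members, and 12 passed an adjusted p of 0.05 in limma's camera test with a preset correlation, 6 higher and 6 lower. None of the 12 held with an estimated correlation, where the adjusted p was between 0.619 and 0.795, and none held with fry (smallest adjusted p = 0.569; 0.756 for change in either direction). No member of any list passed adjusted p 0.05 over all genes, and 0 passed when adjusted over the list alone. Interferon-stimulated genes had the largest difference with all 4 lines, with a median of the mean log2 ratios of 0.70 and 47 of 47 members higher on average (adjusted p = 2.15e-14; adjusted p = 0.619 with an estimated correlation). Without Panc05.04 that median was 1.02, and without Panc8 0.17, then smaller in size than those of the cell cycle lists (G2/M -0.29 and G1/S -0.27). TRIM22, CMPK2, MX1 and IFI44L, all induced by interferon in antiviral defence, had mean log2 ratios of 1.63, 1.29, 1.22 and 1.15. G2/M cell cycle genes had a median of -0.28, with 55 of 56 members lower on average (adjusted p = 1.2e-22; adjusted p = 0.619 with an estimated correlation). Among them CDCA3 had a mean log2 ratio of -0.50, the mitotic kinases PLK1 and AURKA -0.49 each, and GTSE1 -0.46. G1/S cell cycle genes had a median of -0.24, with 47 of 48 members lower (adjusted p = 4.13e-11; adjusted p = 0.639 with an estimated correlation). Without Panc10.05 the G1/S median was -0.03 and the G2/M median -0.17, and without Panc05.04 the G2/M median was -0.40. UHRF1, the thymidylate synthase TYMS, HELLS and the cyclin CCNE1 led the G1/S list, between -0.45 and -0.37.

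The other lists past the preset-correlation threshold had smaller medians. NF-kB and inflammatory cytokine genes had a median of 0.20, with 26 of 31 members higher (adjusted p = 3.74e-04), led by SAA1 and the NF-kB target BIRC3 at 0.67. Mucins and secreted gastrointestinal glycoprotein genes had a median of 0.20 with 16 of 19 higher on average (adjusted p = 0.0018), and PIGR, the polymeric immunoglobulin receptor, was at 0.88. In single lines the mucin median was 0.25 in Panc8, 0.02 in HPAF-II, 0 in Panc05.04 and 0.32 in Panc10.05. Replication-dependent histone genes were at 0.16 with 10 of 13 higher (adjusted p = 0.0182). Epithelial junction and splicing genes were at 0.13 with 21 of 29 higher on average (adjusted p = 0.00563), led by CLDN3 at 0.48 and EPCAM at 0.42. The junction median was 0.11 in Panc8, -0.04 in HPAF-II, 0.08 in Panc05.04 and 0.16 in Panc10.05. Apoptosis regulators were at 0.11 with 26 of 34 higher (adjusted p = 0.00563), led by TNFSF10, the death ligand TRAIL, at 0.97. MYC target genes were at -0.09 with 32 of 42 lower (adjusted p = 0.0118), and cholesterol biosynthesis genes at -0.09 with 21 of 24 lower (adjusted p = 0.00177). Cytosolic ribosomal protein genes were at -0.07 with 55 of 69 lower (adjusted p = 7.11e-04), and reference housekeeping genes at -0.07 with 13 of 16 lower (adjusted p = 0.0118). Of these, NF-kB, MYC target and ribosomal protein genes had an adjusted p of 0.639, 0.795 and 0.795 with an estimated correlation, and the other 6 had 0.619. Several calls were lost when a line was left out, and medians are given here beside the adjusted p. Without Panc8 they were 0.13 for the NF-kB list (adjusted p = 0.299), 0.08 for apoptosis regulators (adjusted p = 0.141), 0.11 for histones (adjusted p = 0.419) and 0.03 for ribosomal proteins (adjusted p = 0.708). Without HPAF-II they were -0.02 for cholesterol biosynthesis (adjusted p = 0.386) and -0.03 for ribosomal proteins (adjusted p = 0.131). Histones were then at 0.25 (adjusted p = 0.101) and housekeeping genes at -0.08 (adjusted p = 0.0706), no smaller in size than with all lines. Without Panc10.05 they were -0.03 for G1/S genes, 0.09 for mucins and 0.04 for MYC targets (adjusted p = 0.122 each). Junction genes were then at 0.04 and housekeeping genes at -0.06 (adjusted p = 0.0644 each), leaving 7 lists past the threshold. The NF-kB median was also 0.46 without Panc05.04 and 0.10 without Panc10.05. The lists of developmental transcription factors, mesenchymal genes and glycolysis and hypoxia genes, which did not pass, had medians, means and test directions that differed in sign.

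**Figure D2:**
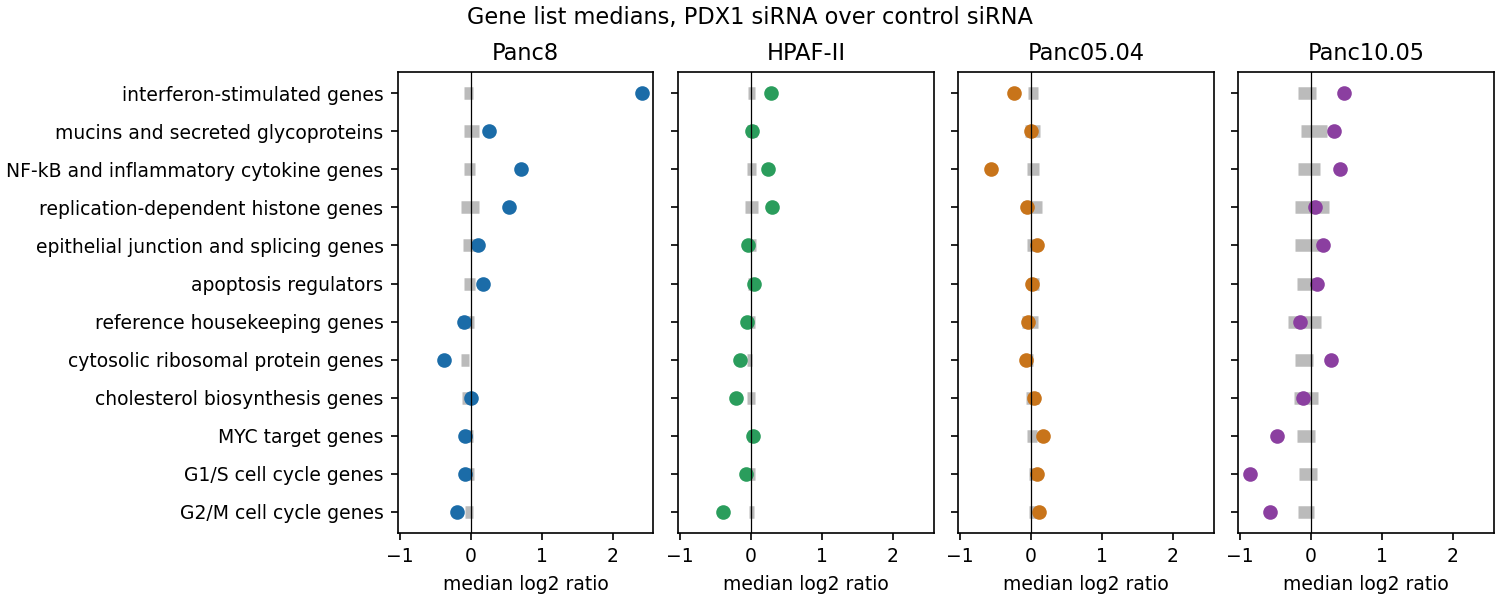
Median log2 ratio of FPKM + 1, PDX1 siRNA over control siRNA, of the members of the 12 lists past the preset-correlation threshold (vertical axis), in each of the 4 lines. Points are list medians in 1 pair of libraries and grey bars the central 95% of medians of 10000 random lists of like expression. The interferon-stimulated list lay at 2.41 in Panc8 and at -0.23 in Panc05.04.

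Within a line, the comparison asked how its own PDX1 siRNA library differed from its own control library, and no test was possible with 1 library per treatment. In Panc8, interferon-induced genes were higher with PDX1 siRNA. The list's median log2 ratio was 2.41, above all 10000 random lists, with 47 of 47 members higher and 44 at least 2-fold higher. IFI6 was at 289.6 FPKM in the control and 3398 FPKM in the PDX1 siRNA library, and ISG15, a ubiquitin-like modifier, at 162 and 1262 FPKM. IFIT1, an RNA-binding antiviral protein, was at 13.9 and 214 FPKM. The antiviral GTPase MX1 was at 11.3 and 146 FPKM, and the chemokine CXCL10 at 9.15 and 110.1 FPKM. RSAD2, CMPK2, TRIM22, USP18, IFIT3, LAMP3 and EPSTI1 made up the rest of the 12 highest protein-coding genes, with FPKM ratios between 8.65 and 26.3. NF-kB and inflammatory cytokine genes had a median of 0.71 with 27 of 31 members higher, and replication-dependent histone genes 0.54 with 11 of 13 higher. Of 24 histone rows only those 13 were high enough to be tested. HIST1H4A (2.63 and 1.32 FPKM) and HIST1H3B (0.799 and 0.594 FPKM) were lower. Classical PDA subtype genes had a median of 0.17 with 25 of 30 higher, and ductal markers 0.15 with 11 of 16 higher. Cytosolic ribosomal protein genes had a median of -0.38 with 68 of 69 lower, and oxidative phosphorylation genes -0.17 with 46 of 50 lower. IGFBP5, an insulin-like growth factor binding protein, was at 134 and 40.5 FPKM, the cytosolic aconitase ACO1 at 22.2 and 6.98 FPKM, and PRR11 at 22.6 and 9.24 FPKM. By size, 197 genes were at least 2-fold higher and 23 at least 2-fold lower, and of the higher genes 44 were members of the interferon-stimulated list. Small RNAs made up 23 of all these genes, and 9 of the lower genes were protein-coding, a count made after seeing the data. The authors' deposited table called 117 genes higher and 6 lower at q of 0.05, with ACO1 at q = 0.00605 and PRR11 at q = 0.017.

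HPAF-II, which had the highest PDX1 level, differed least between its 2 libraries. The log2 ratios of all tested genes had an SD of 0.248, against 0.408 in Panc8. G2/M cell cycle genes were lower, with a median of -0.39, below all random lists, and 54 of 56 members lower. PLK1 was at 31.3 and 20.4 FPKM and AURKA at 52.2 and 36.0 FPKM. Cholesterol biosynthesis genes had a median of -0.21 with 23 of 24 lower, and ribosomal protein genes -0.15 with 61 of 69 lower. Interferon-stimulated genes had a median of 0.29 with 47 of 47 higher and 0 at least 2-fold higher. NF-kB and inflammatory genes were at 0.24 with 25 of 31 higher. The highest protein-coding genes were IGFBP3 at 57.4 and 108 FPKM, the metallothionein MT1X at 18.4 and 35.1, the chemokine CXCL5 at 8.78 and 16.9, the hyaluronan synthase HAS3 at an FPKM ratio of 1.89, and PDK4, which inhibits pyruvate dehydrogenase, at 10.4 and 19.4 FPKM. The lowest were NPB at 5.90 and 2.41 FPKM, the growth factor FGF19 at 33.3 and 15.99, PRAP1 at 10.5 and 5.79, PDX1 itself, and further down SCD, a fatty acid desaturase, at 114 and 68.8 FPKM. By size 22 genes were at least 2-fold higher and 19 lower, of which 24 were small RNAs and 9 protein-coding. The authors' deposited table called 0 genes in this line, with a smallest q of 0.20.

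In Panc05.04 inflammatory genes were lower with PDX1 siRNA. NF-kB and inflammatory cytokine genes had a median log2 ratio of -0.57, below all random lists, with 23 of 31 lower and 9 at least 2-fold lower. The chemokine CCL20 was at 131 and 42.5 FPKM and the cytokine IL6 at 28.5 and 9.79 FPKM. The protease inhibitors SLPI and PI3 were at 83.1 and 20.1 FPKM and at 41.3 and 12.2 FPKM, and the EGF receptor ligand AREG at 8.41 and 1.71 FPKM. The acute-phase gene SAA1, on the same list, was an exception with 136 and 390.1 FPKM. Interferon-stimulated genes had a median of -0.23 with 41 of 47 lower, and basal-like PDA subtype genes -0.11 with 16 of 28 lower. Many basal-like members were under 1 FPKM in this line, such as TP63 at 0.0109 and 0.0135 FPKM and KRT5 at 0 in both libraries. Their ratios pull the median towards 0. The members at 1 FPKM or more in its control were all lower, but choosing members by the control library alone favours lower ones. KRT15, at 0.691 FPKM in the control and 1.34 FPKM with PDX1 siRNA, passed 1 FPKM only in the latter and was higher. YAP/TAZ target genes had a median of 0.17 with 22 of 32 higher, and the highest member ANKRD1 was at 17.1 and 58.8 FPKM. ADM was at 48.9 and 134 FPKM and the heme oxygenase HMOX1 at 80.3 and 194 FPKM. STXBP6, NTN4 and PPME1 had FPKM ratios of 5.51, 4.13 and 3.26. MYC target genes had a median of 0.18 with 38 of 42 higher, G2/M genes 0.11 with 46 of 56 higher, and oxidative phosphorylation genes 0.09 with 42 of 50 higher. By size 46 genes were at least 2-fold higher and 73 lower, of which 42 were small RNAs, and protein-coding genes, counted after seeing the data, numbered 22 and 48. The authors' deposited table called 13 higher and 19 lower, and ANKRD1, SAA1, SLPI, CCL20 and IL6 were each at q = 0.0209.

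Panc10.05, the line with the lowest PDX1 level, had the largest number of 2-fold differences, 359 genes higher and 199 lower, of which 29 were small RNAs. Cell cycle genes were lower, with a G1/S median log2 ratio of -0.86, below all random lists, 48 of 48 members lower and 15 at least 2-fold lower. HELLS was at 26.6 and 9.28 FPKM and UHRF1 at 20.1 and 7.24 FPKM. G2/M genes had a median of -0.57 with 55 of 56 lower, MYC target genes -0.48 with 39 of 42 lower, and YAP/TAZ target genes -0.52 with 21 of 32 lower. The ornithine decarboxylase ODC1 was at 58.5 and 19.1 FPKM and LDHA at 653 and 274 FPKM. The actin crosslinker FLNA was at 214 and 55.8 FPKM, the tubulin TUBB3 at 28.6 and 8.05 FPKM and the transcription factor KLF2 at 74.4 and 18.3 FPKM. The reference gene ACTB was at 3143 and 1601 FPKM and GAPDH at 3604 and 2267 FPKM. GABRP, a GABA receptor subunit, was at 1.97 and 27.8 FPKM, the matrix metalloproteinase MMP7 at 9.30 and 73.4, the arginine synthesis enzyme ASS1 at 6.43 and 61.0 and the transcription factor SOX2 at 1.96 and 15.05 FPKM. Interferon-stimulated genes had a median of 0.47 with 38 of 47 higher, and NF-kB and inflammatory genes 0.41 with 22 of 31 higher. Ribosomal protein genes had a median of 0.29 with 62 of 69 higher, and mucins and secreted glycoproteins 0.32 with 15 of 19 higher. The authors' deposited table called 13 genes higher and 1 lower, the latter NEGR1, with GABRP, ASS1, MMP7 and TRIM22 among the higher genes at q = 0.0441.

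**Figure D3:**
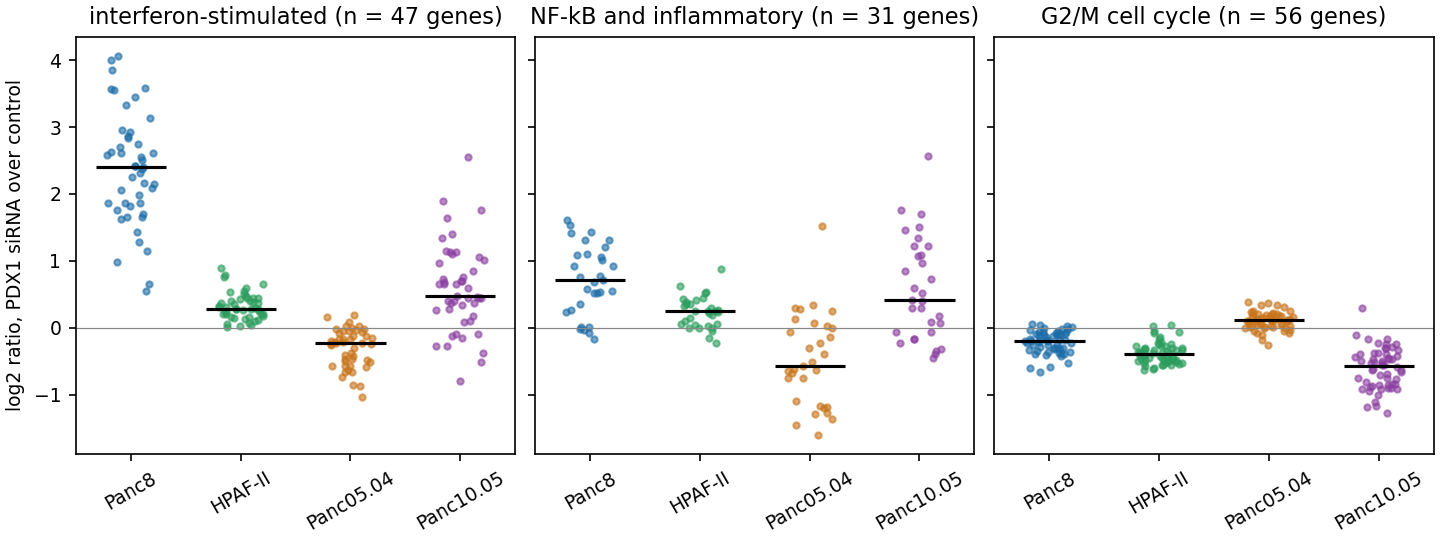
Log2 ratio of FPKM + 1, PDX1 siRNA over control siRNA, of each tested member of 3 gene lists in the 4 lines. Each point is a gene in 1 pair of libraries, spread sideways for legibility, and black bars are medians. The interferon-stimulated genes of Panc8 had a median of 2.41, and the G2/M genes had medians of -0.39 in HPAF-II and 0.11 in Panc05.04.

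The log2 ratios of the 4 lines were nearly uncorrelated. With 1 library per line and treatment, a line's own response cannot be told from a difference between its 2 cultures. Across the 12110 tested genes, which are not independent replicates, Pearson's r between the log2 ratios of a pair of lines was between -0.132 (Panc05.04 and Panc10.05) and 0.149 (Panc8 and HPAF-II), with a median of 0.0501 over the 6 pairs. Spearman's rho was between -0.204 and 0.169 in the same pairs. Panc8 and Panc10.05 shared 43 genes at least 2-fold higher, where independent lists of 186 and 322 genes share 4.95, and 9 genes at least 2-fold lower, where 0.34 were expected. Panc8 and Panc05.04 shared 4 higher genes where 0.614 were expected, and 15 genes were at least 2-fold higher in Panc8 and lower in Panc05.04. Panc05.04 and Panc10.05 shared 7 higher and 5 lower genes, where 1.06 and 0.988 were expected. In that pair 16 genes were lower in Panc05.04 and higher in Panc10.05, and 6 went the reverse way. Panc8 and Panc10.05 had 1 such opposite gene each way. At least 1.5-fold differences in the same direction in 4 of 4 lines were found for 2 higher genes, SAA1 and SNORD3A, and 1 lower gene, SNORA63. These genes were chosen after their values were seen. Shuffling each line's ratios among genes of like expression 1000 times gave at most 1 such gene in each direction. The shuffles and the expected overlaps do not account for genes that vary more than others of like expression. An excess over them therefore does not by itself show a shared response.

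Pancreatic developmental transcription factors, PDX1 among them, showed no common direction, with 10 of 20 members higher and 10 lower on average. The epithelial factor ELF3 had a mean log2 ratio of 0.25, from -0.89 in Panc05.04 to 1.45 in Panc10.05, the pioneer factor FOXA1 0.24 and GATA6 0.23. Marker lists of other cell types had medians near 0 in all 8 libraries. The median FPKM was at most 0.0802 for fibroblast markers, 0.115 for leukocyte markers and 0.131 for endothelial markers, and 0 for endocrine islet genes and acinar enzymes. Single members were well above that, and those given here were chosen after their values were seen. CD74 was at 182 and 389.5 FPKM in Panc10.05, CD68 at 68.7 and 67.0 FPKM in HPAF-II, the endothelial adhesion gene ESAM at 30.3 and 28.4 FPKM in Panc05.04, and the trypsinogen gene PRSS3 at 33.5 and 32.2 FPKM in Panc8.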

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

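Tests of RNA from another line and of length and GC content were written before their results were seen; the other tests in this part were chosen after. Values of 4 lines were checked for a line far from the others in 58 sets (PDX1, named genes across lines, list medians and per-line counts). Of these 58 sets, 5 held such a line, where chance gives about 1 set in 20. The high PDX1 of HPAF-II was counted once for each treatment, and the sets are not independent. No excess over chance is therefore claimed. Genes chosen as extremes of a line were not checked.

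PDX1 in HPAF-II was far above the other 3 lines, at 9.61 FPKM with control siRNA and 5.37 FPKM with PDX1 siRNA. TECPR2 was at a log2 ratio of 0.63 in Panc8, apart from the other lines. The median of cyclin-dependent kinase inhibitors and p53 targets was -0.12 in Panc10.05, apart from values between 0.02 and 0.03 in the other lines. It lay inside the range of random lists in Panc10.05 (-0.175 to 0.126), with 15 members higher and 17 lower. Lists with a median above the central 95% of random lists in 1 line and below it in another are given next, and none of these differences was tested. NF-kB and inflammatory genes differed by 1.28 on the log2 scale between Panc8 and Panc05.04. MYC target genes differed by 0.66 and YAP/TAZ target genes by 0.68 between Panc05.04 and Panc10.05. MAPK output genes differed by 0.38 between Panc8 and Panc10.05, and autophagy and lysosome genes by 0.13 between Panc8 and Panc05.04. Classical PDA subtype genes differed by 0.22 between Panc8 and HPAF-II, and Notch and Wnt target genes by 0.33 between Panc10.05 and HPAF-II. Ribosomal protein genes differed by 0.66 between Panc10.05 and Panc8, and oxidative phosphorylation genes by 0.26 between Panc05.04 and Panc8.

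Interferon-stimulated genes had a median log2 ratio 2.64 higher in Panc8 than in Panc05.04, a difference that was not tested. RNA of another line in the Panc8 PDX1 siRNA library is argued against. Genes at 20 FPKM or more in another line's control and under 1 FPKM in the Panc8 control reached a median of at most 0.0838% of the other line's level, while the interferon-stimulated genes would need a median of at least 313%. The list was not higher in all 4 lines, since its median was -0.23 in Panc05.04, below its random lists. A response to PDX1 loss common to the 4 lines stays open, because the value of each line, Panc8 included, rests on 1 unreplicated pair. A response to the transfected RNA or to the state of the culture may also be the source and cannot be told apart from PDX1 loss with 1 PDX1 siRNA label and untransfected cells not analysed here. The interferon gene IFNL1 was at 0 in the Panc8 control and 2.26 FPKM with PDX1 siRNA, and at 17.2 and 6.60 FPKM in Panc05.04, so it went with the list in both lines.

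G1/S cell cycle genes had a median of -0.86 in Panc10.05, far from the other 3 lines. Transcript length and GC content are argued against as the whole cause, since the median was -0.81 after their trend was removed (48 of 48 members with a length; random lists between -0.159 and 0.074). RNA of another line is argued against by a median share of at most 0.000678% for genes private to another line. A response to PDX1 loss common to the 4 lines stays open: the G2/M median lay below all random lists in 3 lines, at -0.19 in Panc8 with 52 of 56 members lower, -0.39 in HPAF-II and -0.57 in Panc10.05. It was 0.11 in Panc05.04, above the central 95% of its random lists and 0.69 higher than in Panc10.05, an untested difference resting on unreplicated pairs. For this explanation and the same explanation of the interferon-stimulated list, a single line in the other direction was first meant to count against it. After the values were seen, 2 such lines were required. PDX1 was at 0.188 FPKM in the Panc10.05 control, and a difference in culture density or growth between the 2 dishes, for which the labels give no measure, was not tested and could underlie the -0.81 as well.

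Rows listed at 0 in 1 library and at 5 FPKM or more in the other library of the line numbered 38 with a 0 in the control and 45 with a 0 in the PDX1 siRNA library. MIR5047 was at 0 and 17633 FPKM in Panc8, and MIR1282 at 0 and 2596 FPKM in Panc10.05. Of these rows 98.8% were small noncoding RNAs or had a shared symbol, against 2.6% of the other rows at that level, and 0 were protein-coding genes with a symbol of their own. This is consistent with features too short or too similar to be estimated reliably, as the rows went in both directions. SNORA63 and SNORD3A, which stood out across lines, are small RNAs as well.

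Other splits of the 8 libraries that part all 4 pairs number 8 with the real one, too few for a share under 0.05. For genes past adjusted p 0.05, the real split gave 0 and the highest of the others 0, so 8 of 8 splits gave as many, which a real count of 0 makes certain and which says nothing about chance. For gene lists, the real split gave 12 and the highest of the others 17, with the Panc05.04 libraries exchanged, and 2 of 8 splits gave at least 12. Splits that part only 2 pairs compare lines with each other and gave 0 to 11 genes.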

How the results depend on the processing

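Counts over protein-coding genes or without the interferon-stimulated list were chosen after seeing the data. The counts of genes past adjusted p 0.05 across lines were 0 higher and 0 lower under all 14 alternatives. Without the block (line pairing ignored), limma gave 2 genes at an unadjusted p under 0.05 in place of 440, and PDX1 had an exact permutation p of 0.514 at the same mean log2 ratio of -0.52. The PDX1 log2 ratio was between -0.66 and -0.44 when a line was left out, -1.001 with a pseudocount of 0.1 and -0.22 with 5.

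The number of gene lists past the threshold was between 7 (without Panc10.05) and 15 (without Panc05.04), and 0 with an estimated correlation or fry. The MYC target median was between -0.18 and 0.0397 when a line was left out, and the ribosomal protein median between -0.19 and 0.027. Of 143 alternative list values, 19 lost the call, 2 of them with the sign reversed, and the cause was not tested. The histone call was lost without a filter (adjusted p = 0.371) and the junction and mucin calls without the block (adjusted p = 0.642 and 0.0983). The block does not enter a list's median, so the junction and mucin medians stayed at 0.13 and 0.20. The MYC target, ribosomal and housekeeping calls were lost with quantile normalization (adjusted p = 0.0542, 0.0583 and 0.113).

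Counts at least 2-fold higher and lower differed between settings; a lower fold admits more genes by construction, and otherwise the cause was not tested. In Panc8, 66 were lower with a pseudocount of 0.1, 419 and 148 were higher and lower at 1.5-fold, and 9 protein-coding genes were lower. The authors' deposited table called 117 and 6. In HPAF-II the counts were 50 and 43 with a pseudocount of 0.1, 11 and 12 above 5 FPKM, 85 and 67 at 1.5-fold, 3 and 6 for protein-coding genes, and 0 and 0 in the authors' deposited table. In Panc05.04 they were 94 and 152 with a pseudocount of 0.1, 184 and 268 at 1.5-fold, 22 and 48 for protein-coding genes, and 13 and 19 in the authors' deposited table. In Panc10.05 they were 638 and 329 with a pseudocount of 0.1, 1184 and 962 at 1.5-fold, and 13 and 1 in the authors' deposited table. Without the interferon-stimulated list 153 genes remained at least 2-fold higher in Panc8. The median correlation between lines was between 0.0414 and 0.0808 under the alternatives. Depth limits low genes most, as for PDX1 in Panc10.05, and total depth is not given in the sources used here.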

Other observations

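The test of cytoskeletal genes below was chosen after values of that kind had been seen. Beside the lists fixed beforehand, genes of the actin and tubulin cytoskeleton were lower in the Panc10.05 PDX1 siRNA library. After FLNA, ACTB, TUBB3, TUBA1B and LMNA had been seen to be lower, the hypothesis that the gene families as a set were lower was tested on 32 other members, after a first test that had held those 5 genes as well. Their median log2 ratio was -0.51, below random lists of like expression (-0.239 to 0.113), with 27 of 32 lower and 8 at least 2-fold lower. The medians were -0.14 in Panc8, also just below its random lists (-0.132 to 0.0319) with 24 of 32 lower, -0.03 in HPAF-II and 0.03 in Panc05.04. This may be a lower cytoskeletal programme in the Panc10.05 cells, as a hypothesis, but with 1 library per treatment it cannot be separated from a difference between the 2 cultures. In Panc10.05 TUBB4B, a member of the G2/M list, was at 711 and 313 FPKM.

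Epidermal differentiation genes, a set made after some of its members had been seen to differ, had a median log2 ratio of 0.17 in Panc8 with 14 of 18 higher and 6 at least 2-fold higher. In Panc05.04 the median was 0 with 1 of 18 higher and 6 lower, and 4 were at least 2-fold lower, among them SLPI, PI3 and S100A9. In Panc10.05, 4 of the 18 were at least 2-fold higher and 0 at least 2-fold lower. A test of this set was run, came out positive, and is not counted, because the set held the genes that had prompted it.

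Interferon genes themselves were detected, highest in the Panc05.04 control, where IFNL1 was at 17.2, IFNL2 at 4.80 and IFNL3 at 4.02 FPKM. IFNB1 was at 0 and 0.381 FPKM in Panc8 and at 1.497 and 0.672 FPKM in Panc05.04. TLR3, a sensor of double-stranded RNA, was at 5.69 and 13.7 FPKM in Panc8 and at 4.85 and 3.06 FPKM in Panc05.04. The interferon receptor gene IFNAR1 was at 14.5 and 13.9 FPKM in Panc8. These genes were chosen after the values of the interferon-stimulated list were seen.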
